A study of Mus with 8 samples.

How the data were processed

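Spatial expression was measured in 8 sections of pancreatic tumour tissue, 2 each from ND TN, ND STN, DIO TN and DIO STN mice. Per the labels' protocols, paraffin blocks were sectioned to fit slides of 4 capture areas, and the sections were deparaffinised, stained with haematoxylin and eosin and imaged. Per the same protocols, probes were hybridised and captured with a UMI and a spatial barcode, and the libraries were sequenced on a NovaSeq instrument. The values used are UMI counts per gene and spot, made with Space Ranger 1.3.1 per the file headers, on mm10 per the submitters' processing notes, and deposited for spots under tissue. The organism label names the genus only, and mouse gene names and identifiers were used as deposited. Coordinates were taken from a gene table of GRCm38.p6, the assembly that mm10 names. Groups and replicate numbers were taken from the sample titles.

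Counts were summed over all spots under tissue to give 1 library per section, of 20.8 to 68.2 M UMIs (M, 1e6) over 1874 to 4444 spots. Of the genes in the panel, 14952 passed the expression filter (filterByExpr by group, minimum count 10) and 4513 were not tested. Sums were scaled by TMM and fitted with edgeR 4.0.16 (glmQLFit and glmQLFTest, robust) in R 4.3.3, with a mean per group for all 8 sections, so that all groups share an estimate of spread. The common dispersion was 0.0834 with 4 residual degrees of freedom. Tests were 2-sided, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. The 7 comparisons were the diet average (mean of DIO groups minus mean of ND groups), the temperature average (STN minus TN), diet in STN, diet in TN, temperature in ND, temperature in DIO, and the diet by temperature interaction. Each p-value measures the spread between sections, and sections may share animals: the names of the deposited libraries share a code within DIO STN, within ND TN and within ND STN, but not within DIO TN. Comparisons that share sections also share their chance values. Levels in the text are CPM of section totals, while fold changes use TMM scaling. With library size alone, the median log2 fold change of all genes shifted by -0.142 for the diet average, -0.137 for the temperature average, -0.275 for diet in STN, -0.271 for temperature in DIO and -0.268 for the interaction.

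The fit was tested on simulated data before use: counts were drawn from the gene means over sections, the section sizes and the fitted trend of the dispersion, with 100 genes changed 2-fold and 100 changed 4-fold. The simulated sections were independent, with the same spread in all groups. The real sections may share animals and differ in spread, so the real share of false calls may be higher. The diet average recovered 52% of 2-fold and 80% of 4-fold changes with 6 false among 138 calls (14795 genes run). The temperature average recovered 56% and 90% with 18 false among 164 calls (14801 genes run). Diet in STN recovered 34% and 70% with 6 false among 110 (14771 genes run), and diet in TN 27% and 71% with 6 false among 104 (14763 genes run). Temperature in ND recovered 30% and 77% with 3 false among 110 (14789 genes run), and temperature in DIO 32% and 79% with 7 false among 118 (14772 genes run). The interaction recovered 6% and 57% with 4 false among 67 (14767 genes run). A comparison without calls can thus hide most 2-fold changes.

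The test design, the alternatives and 43 gene lists were fixed before the data were examined. The ribosomal protein list has no gene in the panel, so 42 lists were tested; 48 list genes are outside the panel, which holds 0 mitochondrial genes. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the data. Some lists share genes, such as Slc2a1, Atf3, Dusp1, Pdk4, Krt19 and Msln. The panel gives 11 symbols to 22 identifiers, Ddit3 and Aldoa among them; these were kept apart, so that lists are counted by identifier.

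Named genes were chosen by a rule: for each average, up to 12 largest rises and 12 largest falls with an adjusted p under 0.05, a mean log2 CPM of at least 3, the same sign in both single comparisons and no overlap between the 4 sections of a level and the 4 of the other. For the other comparisons up to 6 each way were taken, and no overlap was not demanded for the interaction. Up to 4 members of each called list, and Sox10, Nefl, Th, Dbh, Npy and Adrb3, were given in any case; some other genes fixed in this way are not reported here. Predicted genes without a standard name were passed over.

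For spot measures, spots were thinned to 2000 UMIs and shallower spots left out. A nerve-positive spot had at least 2 UMIs of 15 Schwann cell genes (the list without Pmp22, Ncam1, L1cam, Cnp and Erbb3, which other cells express). Shares and Moran's I were compared between 4 and 4 sections with exact permutation tests (two-sided, 70 splits, smallest possible p 0.0286), and spot shares carry 95% Wilson intervals. Regions came from Leiden clustering (scanpy 1.11.5, leidenalg 0.10.2, Python 3.11.15, resolution 0.5, 2000 variable genes, 20 principal components, 15 neighbours). At resolutions of 0.3 and 0.8 there were 8 and 16 regions. Leading genes were ranked by fold over the other spots with 10 CPM added, among genes seen in at least 50 spots. Acinar-rich spots, with at least 5% of UMIs in the acinar list, numbered 0 in each section for a difference of 0 by diet and by temperature (exact permutation p = 1), so that leaving them out changes no count.

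Alternatives were scaling by RLE or library size alone, no filter, DESeq2 1.42.0, the spots richest in epithelial genes, spots of at least 1000 UMIs, the replicate number as a block, sections of a shared code summed (5 libraries for 4 groups, so that the spread comes from DIO TN alone), a fit of 2 groups, fits of only the 4 sections compared, leaving out each section in turn, and other settings of the spot measures. Others, named with the alternatives' values, were added after the data had been seen. Histology images were not used here.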

Results

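Spatial gene expression was measured in 8 sections of mouse pancreatic tumours. The tumours grew from KPC1199, a mouse line of pancreatic ductal adenocarcinoma, implanted in the pancreas. The mice ate a normal diet (ND) or were obese from their diet (diet-induced obesity, DIO), and were housed at 30 °C, which is thermoneutral for mice (TN), or at 22 °C, which the labels call cold stress (STN). The 4 groups of this crossed design held 2 sections each: ND TN, ND STN, DIO TN and DIO STN. Library names share a code within DIO STN, within ND TN and within ND STN, so the sections of these groups may share an animal. Each n below counts sections, not animals. The assay was Visium for formalin-fixed, paraffin-embedded tissue. In it, pairs of gene-specific probes bind the RNA of a section, and each ligated probe is captured on a printed grid of spots and counted by its unique molecular identifier (UMI). The title of the study concerns obesity and the innervation of pancreatic tumours, and the labels imply a comparison of diets, of temperatures and of their combination.

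Levels are given in counts per M UMIs (M, 1e6) of a section (CPM), and fold changes are from the scaled counts of the test. Tissue covered 1874 to 4444 spots per section, and the section totals ran from 20.8 to 68.2 M UMIs. ND TN 1 and ND TN 2 held 68.2 and 46.2 M, ND STN 1 and ND STN 2 63.8 and 54.2 M, DIO TN 1 and DIO TN 2 61.9 and 49.9 M, and DIO STN 1 and DIO STN 2 44.4 and 20.8 M. The median spot held 2026 UMIs in DIO STN 2, 11357.5 in DIO STN 1 and 15428 to 28592 in the other 6 sections. In DIO STN 2, 34.2% of spots held fewer than 1000 UMIs, against at most 5.18% in any other section.

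The DIO STN sections stood apart from the other 6. Over genes with a mean log2 CPM of at least 3, the median absolute log2 difference was 0.270 between DIO STN 1 and DIO STN 2 and 0.325 to 0.399 between either of them and any other section. Among the other 6 sections it was 0.135 to 0.226. Clustering of the 23592 spots with at least 2000 UMIs gave 11 regions, which are described here by their leading genes and were not tested between groups. Region 3, led by the stress genes Depp1, Fos and Atf3, held 95% of the clustered DIO STN 1 spots, 11.9% of those of DIO STN 2 and at most 0.708% in any other section. Region 9, led by Fabp4, Cd36 and Hp and including Npy among its 10 leading genes, held 86.5% of the clustered DIO STN 2 spots and at most 1.85% elsewhere. Region 8, led by Acod1, Cxcl3 and Rsad2 and including the neutrophil genes S100a8 and S100a9, held 24.5% and 13.2% of spots in DIO TN 1 and DIO TN 2 and at most 0.913% elsewhere. Normal acinar tissue was scarce: no spot had 5% of its UMIs in acinar genes, and a count of 0 allows a share of up to 0.0675% to 0.160% of spots, depending on the section.

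**Figure D1:**
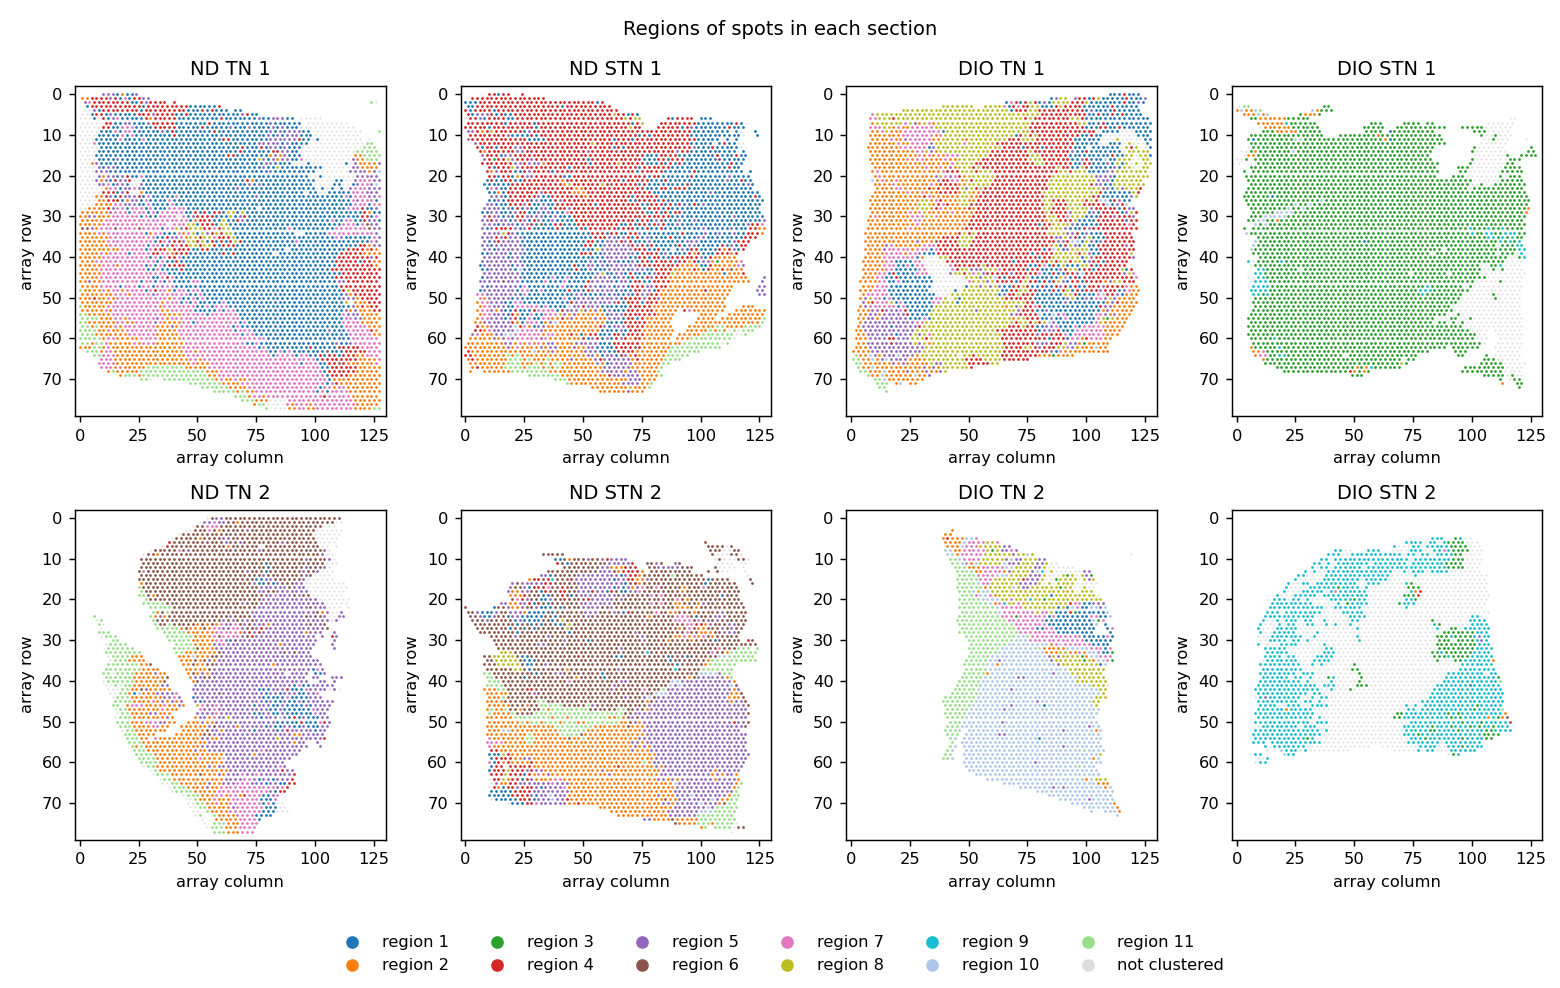
Each map shows the spots of a section at their grid row and column, coloured by the region (1 to 11) that clustering gave them; spots under 2000 UMIs were not clustered. Region 3 covers 95% of the clustered spots of DIO STN 1 and region 9 covers 86.5% of those of DIO STN 2.

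By the average over both temperatures, Gdf15 and Pdk4 were among the genes that were higher in tumours of DIO mice than of ND mice, and 4 class II genes and their regulator Ciita were lower. Gdf15, a stress-induced cytokine of the TGF-beta family (chromosome 8, 70629393 to 70632470, GRCm38.p6), rose 7.83-fold (log2 fold change 2.97, SE 0.21, adjusted p = 0.0203), from 5.27 ± 0.943 CPM (SD, n = 4) in ND to 54.3 ± 48.1 CPM (n = 4) in DIO. Pdk4, a kinase that turns mitochondria from glucose to fatty acid oxidation (chromosome 6, 5483351 to 5496278), rose 9.42-fold (3.24, SE 0.47, adjusted p = 0.0404), from 11.1 ± 8.57 to 80.6 ± 40.4 CPM (n = 4 each). H2-Eb1, a class II histocompatibility chain (chromosome 17, 34305867 to 34316674), fell by 3.32 on the log2 scale (SE 0.49, adjusted p = 0.0413), from 187 ± 89.0 CPM to 16.7 ± 8.74 CPM (n = 4 each). Cd74, the invariant chain that guides class II molecules (chromosome 18, 60803849 to 60812652), fell by 3.12 (SE 0.49, adjusted p = 0.0425), from 1674 ± 702 to 175 ± 106 CPM.

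In all, 201 of 14952 genes tested differed by diet, 145 higher and 56 lower in DIO (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 78 of them by more than 2-fold. The rule that chose the genes named from the largest changes required each to be higher, or lower, in all 4 DIO sections than in all 4 ND sections. Among the largest rises were the neutrophil chemokine Cxcl3 (log2 2.73, SE 0.28), the acyl-CoA thioesterases Acot1 (2.54) and Acot2 (2.02), the lipid droplet gene Hilpda (2.43) and the lipolysis inhibitor G0s2 (2.04). Npy, Fam71f2, Chil1, Aldh1a1 and Osm rose by 2.48, 2.33, 2.09, 2.01 and 2.00. Among the largest falls were H2-Aa (-3.15), H2-Ab1 (-2.96), the B cell and macrophage receptor Cd72 (-2.35), the fractalkine receptor Cx3cr1 (-2.20) and the desaturase Fads2 (-0.96). Fgd2, Mkks, Snn, Lfng and Nradd fell by 1.33, 1.11, 0.95, 0.93 and 0.89.

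Of 42 gene lists tested with camera at a preset correlation, 15 were called by diet, 12 higher and 3 lower in DIO. None of them was called with an estimated correlation. Of the lists called higher, glucocorticoid response genes had the largest median: of 12 measured, 6 rose past the test over all genes and 11 when adjusted over the list alone, with a median log2 fold change of 1.46 (adjusted p = 4.0e-27; adjusted p = 0.121 with an estimated correlation). They included Tsc22d3 (1.71, SE 0.14), Per1 (1.17) and Klf9 (0.87), all direct targets of the glucocorticoid receptor. The glucocorticoid list held 7481 and 15386 CPM in DIO STN, 2306 and 5700 in DIO TN 1 and DIO TN 2, and 1825 to 2793 in ND. DIO TN 1 thus lay within the ND range. Of 15 immediate early and stress genes, 6 rose over all genes, and 9 rose and 2 fell adjusted over the list alone (median 0.72, adjusted p = 3.87e-11; adjusted p = 0.121 with an estimated correlation). Fos rose by 1.86, Dusp1 by 1.72 and Fosb by 1.47. Of 17 unfolded protein response genes, 4 rose over all genes, and 7 rose and 2 fell adjusted over the list alone (median 0.20, adjusted p = 3.09e-05; adjusted p = 0.121 with an estimated correlation). They were Atf3 (1.78), Atf4 (0.53) and the stress factor Ddit3, which the panel lists under 2 identifiers that rose by 1.24 and 1.28. Both of these last lists were high in the DIO STN sections only: immediate early and stress genes held 5581 and 5449 CPM there, 2263 and 2065 in DIO TN and 1990 to 2487 in ND. Unfolded protein response genes held 4905 and 4339 CPM in DIO STN, 2814 and 2780 in DIO TN and 2966 to 3209 in ND.

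Hypoxia genes were higher in DIO as a list, with 1 of 14 past the test over all genes, 8 adjusted over the list alone and a median of 0.81 (adjusted p = 1.75e-10; adjusted p = 0.451 with an estimated correlation). This list was raised in DIO STN only, at 5388 and 8630 CPM. In DIO TN it held 2059 and 1850 CPM, within the ND range of 1644 to 3242. Adm, a vasodilator peptide induced by low oxygen, rose by 2.46 (SE 0.33), while the glucose transporter Slc2a1 was at 1.15 (adjusted p = 0.0522) and Vegfa at 1.00. Among 12 glycolysis genes, counted by identifier with Aldoa under 2, Gpi1 rose by 0.82 over all genes and 5 rose adjusted over the list alone (median 0.46, adjusted p = 5.05e-06; adjusted p = 0.528 with an estimated correlation). Glycolysis genes held 7039 and 9285 CPM in DIO STN, but 4099 and 4426 in DIO TN, within the ND range of 3972 to 5325. Of 16 fatty acid uptake and oxidation genes, 3 rose over all genes, and 8 rose and 1 fell adjusted over the list alone (median 0.28, adjusted p = 2.49e-06; adjusted p = 0.451 with an estimated correlation). They were Pdk4, Cpt1a (1.04), the gate of mitochondrial fatty acid import, and Acadl (0.98), an acyl-CoA dehydrogenase. Adipocyte markers moved with these genes: none of 15 passed over all genes and 7 rose adjusted over the list alone (median 0.95, adjusted p = 0.000250; adjusted p = 0.614 with an estimated correlation). That list held 1360 and 687 CPM in DIO STN 2 and DIO TN 2, 337 and 220 CPM in DIO STN 1 and DIO TN 1, and 200 to 290 CPM in the ND sections.

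Immune lists went both ways. Of 16 antigen presentation genes, 5 fell over all genes and 9 adjusted over the list alone (median -0.97, adjusted p = 1.08e-11; adjusted p = 0.497 with an estimated correlation). These were H2-Eb1, H2-Aa, Cd74, H2-Ab1 and Ciita, the master regulator of class II transcription (-3.17, SE 0.42). None of 17 T and NK cell markers passed over all genes and 11 fell adjusted over the list alone (median -2.23, adjusted p = 1.75e-10; adjusted p = 0.497 with an estimated correlation). The T cell receptor chain gene Cd3e was at -3.19 (adjusted p = 0.0635), and Cd3d was at -3.50 (adjusted p = 0.0621). None of 12 dendritic cell markers passed over all genes and 6 fell adjusted over the list alone (median -1.61, camera adjusted p = 3.44e-05, or 0.528 with an estimated correlation), with Itgax at -2.28 (adjusted p = 0.0618). The total of the dendritic list overlapped between the diets. It was 387 and 331 CPM in DIO STN, 472 and 357 in DIO TN and 394 to 451 in ND. Of 14 neutrophil markers, Mmp8, a neutrophil collagenase, rose by 2.67 (SE 0.33) over all genes, and 5 rose and 1 fell adjusted over the list alone (median 0.65, adjusted p = 0.00166; adjusted p = 0.614 with an estimated correlation). Retnlg was at 3.36 (adjusted p = 0.0516) and S100a9 at 2.00 (adjusted p = 0.0640). The neutrophil list held 2077 and 1382 CPM in DIO STN 2 and DIO TN 1. In DIO STN 1 and DIO TN 2 it held 678 and 630 CPM, within the ND range of 505 to 773 CPM.

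Other lists called by diet were those of epithelial, mesenchymal, mesothelial and sympathetic genes. The epithelial and mesothelial totals were raised in DIO STN only. In DIO TN the epithelial list held 15558 and 13695 CPM, within the ND range of 13339 to 15983. The mesothelial list held 2430 and 2377 CPM there, within the ND range of 1944 to 2544. Of 15 ductal and tumour epithelial markers, Krt8 rose by 0.71 over all genes and 4 adjusted over the list alone (median 0.30, adjusted p = 0.0112; adjusted p = 0.575 with an estimated correlation). Of 13 epithelial-mesenchymal transition genes, Prrx1 alone rose, by 1.18, both ways of adjustment (median 0.16, adjusted p = 0.0209; adjusted p = 0.700 with an estimated correlation). None of 11 mesothelial markers passed over all genes and 2 rose adjusted over the list alone (median 0.23, adjusted p = 0.0187; adjusted p = 0.574 with an estimated correlation). Of 8 sympathetic neurotransmitter genes, Npy rose and no other passed (median 0.28, adjusted p = 0.0370; adjusted p = 0.451 with an estimated correlation). The count of 201 rested on single sections: it was 15 without DIO STN 2, 3 without DIO TN 1, 3 without DIO TN 2, 23 without ND STN 1, 2 without ND STN 2, and 0 without ND TN 1 or ND TN 2, so that no gene named here passed without either ND TN section. It was 3370 at an unadjusted p under 0.05, 1661 by DESeq2, 795 (159 higher and 636 lower) with library size as the only scaling, 1 in a fit of 2 groups, and 0 with sections of a shared code summed, which leaves 5 libraries for 4 groups and few calls possible. The split was 98 higher and 134 lower without the expression filter, and 867 and 794 by DESeq2.

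**Figure D2:**
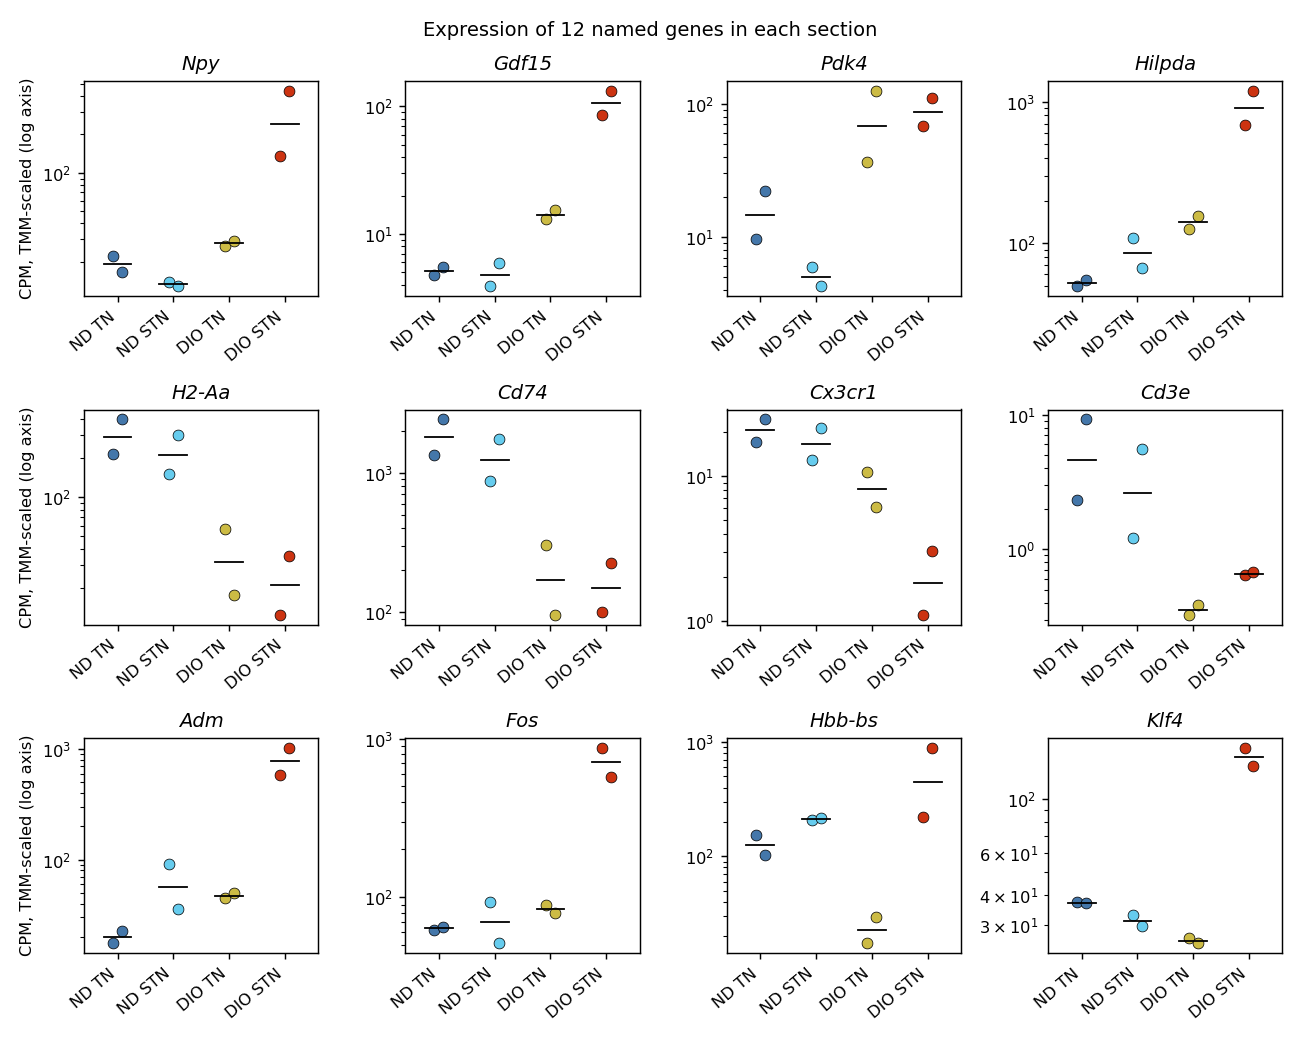
Scaled level (TMM-scaled CPM, log axis) of 12 named genes, with a point per section, a bar at the geometric mean of a group, and the groups ND TN, ND STN, DIO TN and DIO STN along the horizontal axis. Cd74 lies at 95.6 to 304 scaled CPM in the DIO sections and at 867 to 2417 in the ND sections.

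By the average over both diets, Adm and Efna1 were higher and Hist1h1a was lower in tumours of mice housed at 22 °C. Adm (chromosome 7, 110627657 to 110629820) rose 7.34-fold (log2 2.88, SE 0.33, adjusted p = 0.0479), from 35.2 ± 16.7 CPM in TN to 381 ± 393 CPM in STN (SD, n = 4 each). Efna1, an ephrin ligand of the cell surface (chromosome 3, 89271730 to 89280951), rose by 1.57 (SE 0.15, adjusted p = 0.0427), from 156 ± 36.8 to 463 ± 245 CPM. The histone gene Hist1h1a, which is made in dividing cells, fell by 0.70 (adjusted p = 0.0479), from 139 ± 8.68 to 82.8 ± 33.1 CPM.

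Of 14952 genes, 48 differed by temperature, 40 higher and 8 lower in STN (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). By the named-gene rule these were, among the rises, the Ddit3 identifier ENSMUSG00000116429 (1.68), the p53 targets Btg2 (1.36) and Cdkn1a (1.26), Cited2 (1.22), the hexokinase Hk2 (0.97), Ypel5 (0.80) and the chromatin protein Hmga2 (0.74). Besides Hist1h1a, Lyar and Rbm45 fell by 0.65 and 0.62. The rule required each of these to lie higher, or lower, in all 4 STN sections than in all 4 TN sections.

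Of the 42 lists, 11 were called by temperature with the preset correlation and none with an estimated correlation. Of 14 hypoxia genes, Adm and Slc2a1 (1.5) rose over all genes and 10 rose adjusted over the list alone (median 1.31, adjusted p = 4.65e-23; adjusted p = 0.213 with an estimated correlation). The hypoxia list held 5388 and 8630 CPM in DIO STN, 3242 and 1903 in ND STN, 2059 and 1850 in DIO TN, and 1644 and 1800 in ND TN. Of 12 glycolysis genes, 2 rose over all genes and 7 adjusted over the list alone (median 0.61, adjusted p = 1.71e-12; adjusted p = 0.389 with an estimated correlation). Of 15 immediate early and stress genes, 4 rose over all genes, Atf3 (1.77), Fos (1.64), Fosb (1.90) and Dusp1 (1.54), and adjusted over the list alone 9 rose and 1 fell (median 0.68, adjusted p = 2.91e-14; adjusted p = 0.0820 with an estimated correlation). Of 17 unfolded protein response genes, 3 rose over all genes, and 6 rose and 1 fell adjusted over the list alone (median 0.19, adjusted p = 2.81e-08; adjusted p = 0.0820 with an estimated correlation), with the chaperone Hspa5 at 0.53 (adjusted p = 0.0530). Glucocorticoid response genes had 1 of 12 past the test and 5 adjusted over the list alone (median 0.41, adjusted p = 2.22e-06; adjusted p = 0.389 with an estimated correlation). The glucocorticoid list held 1825 and 1837 CPM in ND STN, below all TN sections (2306 to 5700), and 7481 and 15386 in DIO STN. The immediate early list held 2487 and 1990 CPM in ND STN, 2014 and 2245 in ND TN, and 5581 and 5449 in DIO STN. Unfolded protein response genes held 2966 and 2983, 3134 and 3209, and 4905 and 4339 CPM in that order. The rise of these lists in STN thus came from the DIO STN sections.

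Other lists moved with temperature without a member past the test over all genes. Erythrocyte genes had a median of 2.66 and 6 of 7 rose adjusted over the list alone (adjusted p = 6.52e-15; adjusted p = 0.210 with an estimated correlation). The haemoglobin gene Hbb-bs stood at 350 ± 275 CPM in STN and 79 ± 66.6 CPM in TN (SD, n = 4 each; adjusted p = 0.0660). Skeletal muscle genes, a sign of adjoining muscle in a section, had a median of -2.04 with 1 of 13 lower adjusted over the list alone (adjusted p = 2.56e-07; adjusted p = 0.587 with an estimated correlation). That list held 14.4 to 553 CPM in STN sections and 408 to 2803 CPM in TN sections. Of 17 proliferation genes, 5 fell adjusted over the list alone (median -0.32, adjusted p = 2.08e-05; adjusted p = 0.389 with an estimated correlation), with the replication helicase gene Mcm5 at -0.66 (adjusted p = 0.0570). Interferon response genes had a median of -0.85 and none of 15 passed either way (adjusted p = 1.96e-05; adjusted p = 0.728 with an estimated correlation). Epithelial markers had 3 of 15 higher adjusted over the list alone (median 0.37, adjusted p = 1.59e-05; adjusted p = 0.389 with an estimated correlation). Mesothelial markers had 1 of 11 (median 0.96, adjusted p = 0.00224; adjusted p = 0.389 with an estimated correlation). In ND, epithelial, mesothelial and proliferation totals hardly differed by temperature, and the DIO STN sections stood apart. Epithelial markers held 15983 and 13339 CPM in ND STN, 15608 and 13767 in ND TN, and 22202 and 19065 in DIO STN. Mesothelial markers held 2544 and 1944, 2530 and 2045, and 3943 and 3755 CPM in that order. Proliferation genes held 1122 and 1338, 1195 and 1390, and 760 and 779 CPM. The count of 48 was 6 without DIO STN 1, 2 without ND STN 1, 26 without ND STN 2, and 0 without DIO STN 2, DIO TN 1, DIO TN 2, ND TN 1 or ND TN 2. It was 2834 at an unadjusted p under 0.05, 1220 by DESeq2, 312 (67 higher and 245 lower) with library size as the only scaling, 2 with sections of a shared code summed and 0 in a fit of 2 groups. The split was 44 higher and 36 lower without the expression filter, and 637 and 583 by DESeq2.

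**Figure D3:**
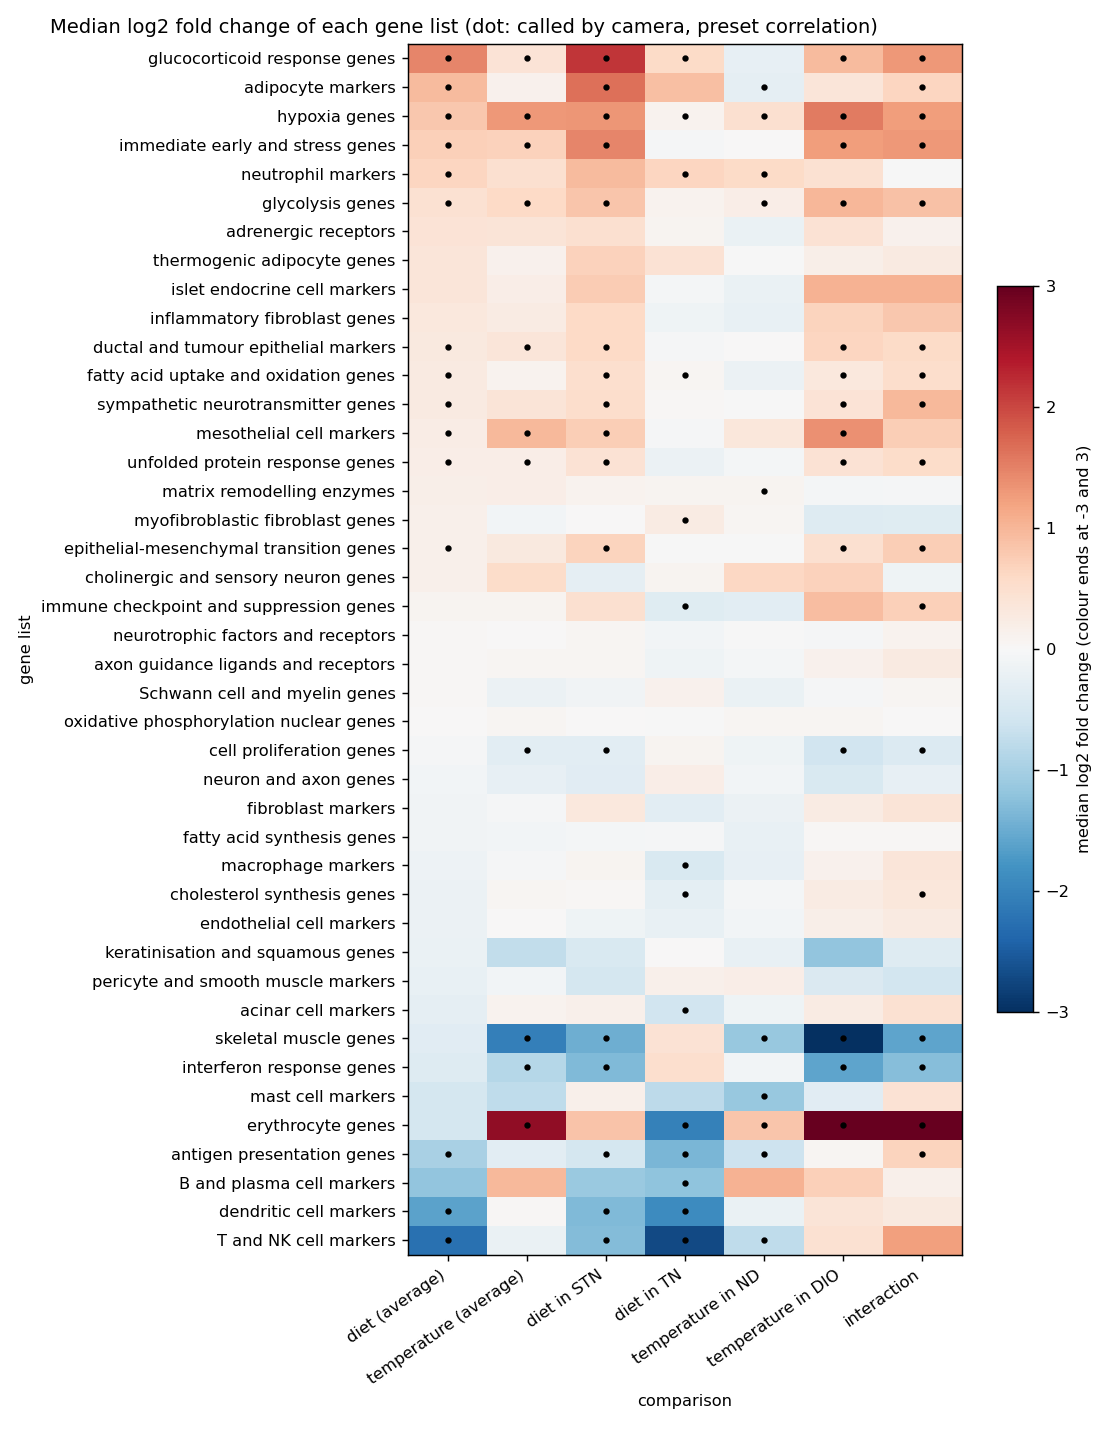
Median log2 fold change of the gene lists (vertical axis) in each comparison (horizontal axis), with colour giving the median up to 3 either way and a dot where camera with the preset correlation called the list. The hypoxia list reaches 1.57 and the erythrocyte list 4.33 for temperature in DIO.

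Within STN, the diets were far apart. Gdf15 rose 22.2-fold in DIO (log2 4.47, SE 0.31, adjusted p = 0.00755), from 5.12 ± 1.48 to 93.6 ± 27.1 CPM (SD, n = 2 each). Npy, a peptide of sympathetic neurons and of some other cells (chromosome 6, 49822710 to 49829507), rose 21.6-fold (4.43, SE 0.54, adjusted p = 0.0115), from 13.9 ± 0.871 to 247 ± 183 CPM. The immediate early transcription factor Fos (chromosome 12, 85473890 to 85477274) rose by 3.32 (SE 0.33), from 76.1 ± 31.8 to 628 ± 197 CPM. Ccr2, the receptor that brings monocytes into tissue, fell by 3.30 (SE 0.68, adjusted p = 0.0301), from 30.9 ± 15.7 to 2.62 ± 1.06 CPM.

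In STN 1607 genes differed by diet, 825 higher and 782 lower in DIO, 670 of them by more than 2-fold (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The fit gives all groups a shared spread, but DIO STN varied more. The SD of log2 CPM within a group, pooled over genes, was 0.700 in DIO STN and 0.441 to 0.487 in the other groups. The adjusted p of this comparison, and of temperature in DIO, may thus be too small. Other large rises were those of Pdk4 (4.12), Retnlg (3.71), Adm (3.68) and the metallothionein Mt2 (3.62). Large falls were those of H2-Aa (-3.26), Cx3cr1 (-3.09), H2-Eb1 (-3.02), Cd74 (-3.0) and Cd72 (-2.93). Of the 42 lists 17 were called, 11 higher and 6 lower, and none with an estimated correlation. Of 12 glucocorticoid response genes, 11 rose over all genes and 11 adjusted over the list alone (median 2.14, adjusted p = 2.92e-21; adjusted p = 0.179 with an estimated correlation), Tsc22d3 by 2.46 and Per1 by 2.02. Of 15 immediate early and stress genes, 10 rose over all genes, and 11 rose and 2 fell adjusted over the list alone (median 1.47, adjusted p = 1.44e-13; adjusted p = 0.0756 with an estimated correlation). Of 17 unfolded protein response genes, 6 rose over all genes, and 8 rose and 1 fell adjusted over the list alone, Hspa5 by 1.09 (median 0.43, adjusted p = 1.39e-07; adjusted p = 0.0756 with an estimated correlation). Of 14 hypoxia genes, 6 rose over all genes and 10 adjusted over the list alone, Slc2a1 by 2.13, Ndrg1 by 2.99 and Vegfa by 1.64 (median 1.33, adjusted p = 5.63e-10; adjusted p = 0.472 with an estimated correlation). Of 12 glycolysis genes, 5 rose over all genes and 8 adjusted over the list alone (median 0.83, adjusted p = 6.99e-07; adjusted p = 0.536 with an estimated correlation). Of 16 fatty acid uptake and oxidation genes, 5 rose over all genes, and 8 rose and 1 fell adjusted over the list alone, Cpt1a by 1.56 and Hadha by 1.06 (median 0.51, adjusted p = 2.52e-05; adjusted p = 0.472 with an estimated correlation). The adipocyte markers Pparg (1.66) and Pnpla2 (1.00) rose over all genes and over the list alone (median 1.66, adjusted p = 0.00149; adjusted p = 0.832 with an estimated correlation).

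Among other lists in STN, 4 of 15 epithelial markers rose over all genes and 6 adjusted over the list alone, Krt8 by 1.61 (median 0.61, adjusted p = 0.000417; adjusted p = 0.531 with an estimated correlation). Of 13 epithelial-mesenchymal transition genes, 4 rose over all genes, and 5 rose and 1 fell adjusted over the list alone, Vim by 1.64 and Lox by 2.53 (median 0.67, adjusted p = 0.00483; adjusted p = 0.832 with an estimated correlation). Of 11 mesothelial markers 2 rose, both ways of adjustment (median 0.73, adjusted p = 0.0213; adjusted p = 0.667 with an estimated correlation). Of 8 sympathetic neurotransmitter genes only Npy passed (median 0.53, adjusted p = 0.0215; adjusted p = 0.472 with an estimated correlation). Antigen presentation genes had 4 of 16 lower over all genes and 6 adjusted over the list alone (median -0.53, adjusted p = 0.00944; adjusted p = 0.870 with an estimated correlation). Dendritic cell markers had Itgax alone lower, at -3.27 (median -1.32, adjusted p = 0.0473; adjusted p = 0.832 with an estimated correlation). Proliferation genes had 2 of 17 lower over all genes and 5 adjusted over the list alone, Mcm5 by -0.87 (median -0.32, adjusted p = 0.0386; adjusted p = 0.832 with an estimated correlation). T and NK cell markers (median -1.30, adjusted p = 0.00644) and interferon response genes (median -1.33, adjusted p = 0.00479) had no member past the test either way, and both had adjusted p = 0.832 with an estimated correlation. Skeletal muscle genes likewise had none (median -1.46, adjusted p = 0.0143; adjusted p = 0.874 with an estimated correlation). The count of 1607 was 1048 without DIO STN 1, 695 without DIO STN 2, 939 without DIO TN 1, 893 without DIO TN 2, 93 without ND STN 1, 5 without ND STN 2 and 1070 without ND TN 1. It was 3113 by DESeq2, 3137 (486 higher and 2651 lower) with library size as the only scaling, and by edgeR 0 with only the 4 STN sections or with sections of a shared code summed, against 4483 at an unadjusted p under 0.05. Without the expression filter, 469 were higher and 1171 lower.

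Within TN no gene passed the test for diet by edgeR; 773 had an unadjusted p under 0.05, the smallest adjusted p was 0.396, and DESeq2 called 77. Cd74 stood at 209 ± 154 CPM in DIO TN and 1982 ± 827 CPM in ND TN (SD, n = 2 each; log2 -3.23, adjusted p = 0.865). Of 16 antigen presentation genes 8 fell adjusted over the list alone (median -1.38, adjusted p = 1.22e-28; adjusted p = 0.435 with an estimated correlation), and of 17 T and NK cell markers 10 did (median -2.70, adjusted p = 9.92e-21; adjusted p = 0.435 with an estimated correlation). Erythrocyte genes had 6 of 7 lower adjusted over the list alone (median -2.03, adjusted p = 5.03e-13; adjusted p = 0.435 with an estimated correlation), with Hbb-bs at 24.3 ± 8.92 CPM in DIO TN and 134 ± 35.9 CPM in ND TN (n = 2 each). Glucocorticoid response genes had 2 of 12 higher adjusted over the list alone (median 0.57, camera adjusted p = 8.60e-10, or 0.435 with an estimated correlation). Their total was 2306 and 5700 CPM in DIO TN 1 and DIO TN 2 and 2793 and 2625 CPM in ND TN, so that it was raised in DIO TN 2 only. Neutrophil markers had 1 of 14 higher, Mmp8 (median 0.65, camera adjusted p = 3.74e-05, or 0.586 with an estimated correlation). Fatty acid uptake and oxidation genes had 1 of 16 higher adjusted over the list alone (median 0.05, adjusted p = 0.0147; adjusted p = 0.613 with an estimated correlation). Immune checkpoint genes had 1 of 14 lower, Lag3 (median -0.35, adjusted p = 0.0404; adjusted p = 0.781 with an estimated correlation).

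In the other lists called for diet in TN no member passed either way. Lower as lists were dendritic cell markers (median -1.88, adjusted p = 1.65e-08; adjusted p = 0.435 with an estimated correlation), cholesterol synthesis genes (-0.30, adjusted p = 8.61e-07; adjusted p = 0.586 with an estimated correlation) and B and plasma cell markers (-1.21, adjusted p = 0.00223; adjusted p = 0.603 with an estimated correlation). Macrophage markers (-0.45, adjusted p = 0.0131; adjusted p = 0.803 with an estimated correlation) and acinar markers (-0.58, adjusted p = 0.0451; adjusted p = 0.603 with an estimated correlation) were lower too. Higher were myofibroblastic fibroblast genes (0.25, adjusted p = 0.0131; adjusted p = 0.586 with an estimated correlation) and hypoxia genes (0.10, adjusted p = 0.0496; adjusted p = 0.803 with an estimated correlation). The 8 lists called by the diet average but not in TN were immediate early and stress genes (-0.03, adjusted p = 0.871), unfolded protein response genes (-0.19, adjusted p = 0.496), glycolysis genes (0.11, adjusted p = 0.496), epithelial markers (-0.04, adjusted p = 0.494), mesothelial markers (-0.04, adjusted p = 0.376), sympathetic neurotransmitter genes (0.04, adjusted p = 0.922), epithelial-mesenchymal transition genes (-0.0019, adjusted p = 0.922) and adipocyte markers (0.89, adjusted p = 0.0696). Of the 1607 genes called for diet in STN, 890 (55.4%) had the same sign in TN, and their median log2 fold change in the called direction was 0.91 in STN and 0.02 in TN, comparisons that share no section. The genes were chosen by the STN test, which raises the STN median but not the TN median.

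Within DIO, the cold-housed sections differed from the thermoneutral ones in 1562 genes, 772 higher and 790 lower in STN (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Of these genes, 1088 were also among the 1607 called for diet in STN, all with the same sign, where independent calls would share 83.9. Both comparisons rest on the same DIO STN sections, so they are not separate evidence for diet and for cold. Hbb-bs (chromosome 7, 103826523 to 103827928) rose 23.9-fold (log2 4.58, SE 0.68, adjusted p = 0.0164), from 24.3 ± 8.92 to 478 ± 402 CPM (SD, n = 2 each), and Hba-a2 rose by 4.33. Adm rose by 4.09 (SE 0.50), from 49.4 ± 3.88 to 695 ± 256 CPM. Rnf186, an intestinal ubiquitin ligase, rose by 4.0, and the gastric gland mucin Muc6 by 3.92. The falls were those of Cym (-2.95), Ppid (-2.17), Dzip3 (-2.10), Nanos3 (-2.04), Riox2 (-1.94) and Adam4 (-1.91).

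Of the 42 lists, 14 were called for temperature in DIO and none with an estimated correlation. Of 14 hypoxia genes, 9 rose over all genes and 12 adjusted over the list alone (median 1.57, adjusted p = 6.51e-15; adjusted p = 0.341 with an estimated correlation), Ndrg1 by 3.47 and Slc2a1 by 2.48. Of 12 glycolysis genes, 6 rose over all genes and 10 adjusted over the list alone (median 1.00, adjusted p = 1.06e-09; adjusted p = 0.344 with an estimated correlation). Of 15 immediate early and stress genes, 9 rose and 1 fell over all genes, and 10 rose and 1 fell adjusted over the list alone, Fosb by 3.77 (median 1.26, adjusted p = 9.89e-15; adjusted p = 0.0750 with an estimated correlation). Of 17 unfolded protein response genes 7 rose, both ways of adjustment, Hspa5 by 1.19 (median 0.44, adjusted p = 2.27e-09; adjusted p = 0.0750 with an estimated correlation). Of 12 glucocorticoid response genes, 5 rose over all genes and 7 adjusted over the list alone (median 0.94, adjusted p = 1.27e-09; adjusted p = 0.341 with an estimated correlation). Of 7 erythrocyte genes 6 rose, both ways (median 4.33, adjusted p = 1.07e-09; adjusted p = 0.341 with an estimated correlation), and this list held 318 and 1170 CPM in DIO STN, 29.4 and 52.3 CPM in DIO TN and 163 to 358 CPM in ND. Of 15 epithelial markers, 4 rose over all genes and 8 adjusted over the list alone (median 0.65, adjusted p = 7.93e-06; adjusted p = 0.341 with an estimated correlation).

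Proliferation genes fell: 5 of 17 over all genes and 7 adjusted over the list alone, Mcm5 by 1.17 and Mcm3 by 0.86 (median -0.57, adjusted p = 6.58e-05; adjusted p = 0.547 with an estimated correlation). None of 15 interferon response genes passed over all genes and 4 fell adjusted over the list alone (median -1.58, adjusted p = 1.46e-05; adjusted p = 0.744 with an estimated correlation). Skeletal muscle genes had Tnni2 lower, by 1.89 (median -3.23, adjusted p = 5.99e-05; adjusted p = 0.744 with an estimated correlation). Epithelial-mesenchymal transition genes had 3 of 13 higher (median 0.48, adjusted p = 0.0124; adjusted p = 0.754 with an estimated correlation), mesothelial markers 2 of 11 (median 1.37, adjusted p = 0.0124; adjusted p = 0.547 with an estimated correlation) and sympathetic neurotransmitter genes 2 of 8, Npy (3.37) and the decarboxylase Ddc (1.82) (median 0.41, adjusted p = 0.0309; adjusted p = 0.341 with an estimated correlation). In these 3 lists the counts were alike both ways. Of 16 fatty acid uptake and oxidation genes, 4 rose over all genes, and 5 rose and 1 fell adjusted over the list alone (median 0.32, adjusted p = 0.0341; adjusted p = 0.744 with an estimated correlation). The count of 1562 was 263 without DIO STN 2, 0 without DIO TN 1 or DIO TN 2, 568 without ND STN 1, 645 without ND STN 2, 905 without ND TN 1 and 918 without ND TN 2. It was 4378 at an unadjusted p under 0.05, 2999 by DESeq2, 2901 (411 higher and 2490 lower) with library size as the only scaling, 28 with sections of a shared code summed and 26 with only the 4 DIO sections. Without the expression filter, 434 were higher and 1012 lower.

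Within ND, no gene passed the test for temperature by edgeR; 387 had an unadjusted p under 0.05, and DESeq2 called 3. Hypoxia genes were higher at 22 °C as a list, with 1 of 14, Ankrd37 (2.06, SE 0.38), past the test adjusted over the list alone (median 0.48, adjusted p = 2.85e-10; adjusted p = 0.822 with an estimated correlation). Immediate early and stress genes (0.02, adjusted p = 0.684), unfolded protein response genes (-0.07, adjusted p = 0.975) and glucocorticoid response genes (-0.25, adjusted p = 0.0872), which were called for temperature in DIO, were not called here. No member of the other 9 lists called passed either way. Antigen presentation genes were lower (-0.62, adjusted p = 3.59e-07; adjusted p = 0.822 with an estimated correlation), as were mast cell markers (-1.15, adjusted p = 0.000564; adjusted p = 0.751 with an estimated correlation). So were skeletal muscle genes (-1.14, adjusted p = 0.00174), T and NK cell markers (-0.77, adjusted p = 0.00961) and adipocyte markers (-0.27, adjusted p = 0.0224), each with adjusted p = 0.888 with an estimated correlation. Erythrocyte genes (0.83, adjusted p = 1.55e-05) and matrix remodelling enzymes (0.09, adjusted p = 0.0101) were higher, both with adjusted p = 0.822 with an estimated correlation. Glycolysis genes (0.19, adjusted p = 0.00120) and neutrophil markers (0.57, adjusted p = 0.00167) were higher, both with adjusted p = 0.888 with an estimated correlation. Of the 1562 genes called for temperature in DIO, 773 (49.5%) had the same sign in ND, with a median in the called direction of 0.90 in DIO and of -0.0028 in ND. The DIO median is raised by the choice of the genes in DIO.

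The diet by temperature interaction, which tests whether the effect of diet differed between temperatures, was past the threshold for a single gene. Klf4, a transcription factor of epithelial differentiation and stress (chromosome 4, 55527137 to 55532475), stood at 130 ± 18.9 CPM in DIO STN, 32.8 ± 2.42 in ND STN, 26.9 ± 0.875 in DIO TN and 39.1 ± 0.409 in ND TN (SD, n = 2 each; interaction log2 2.79, SE 0.19, adjusted p = 0.0233). Hspa5, Fosb, Herpud1, Per1 and Krt8 followed at interactions of 1.32, 3.74, 2.37, 1.69 and 1.81, each with adjusted p = 0.0635. Npy was at 3.92 (adjusted p = 0.0741) and Ndrg1 at 3.47 (adjusted p = 0.0745). In all 2788 genes had an unadjusted p under 0.05, and DESeq2 called 1280. The single call was 4 without DIO STN 1 and 0 without any of the ND or DIO TN sections in turn, 258 (41 higher and 217 lower) with library size as the only scaling, and 0 with sections of a shared code summed. Library numbers place DIO STN and ND TN in a set of 4 and the other groups in another, and the fiducial frame measured 212.903 to 212.981 pixels in the former and 212.874 to 212.897 pixels in the latter. If these sets are slides, the fit cannot separate slide from interaction, and each comparison within a diet or a temperature crosses the slides, while both averages are balanced over them. Across the same sets, the 1607 genes called for diet in STN differed between ND TN and ND STN by a median of 0.0660 in the called direction, against 0.907 for diet, the comparison that chose them.

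Nerve genes were low in all sections. The Schwann cell transcription factor Sox10 had 0 to 19 UMIs per section. Of the axon gene Nefl there were 3 to 29 UMIs, and of the catecholamine enzymes Th and Dbh 0 to 9 and 0 to 4. Th and Dbh were too low to be tested. As a background, the 1178 olfactory and vomeronasal receptor genes of the panel had a mean of 10.6 UMIs in DIO STN 1 and 0.404 to 3.72 in the other sections. The 9 Th, 4 Dbh and 7 Nefl UMIs of DIO STN 1 lay below it, and its 11 Sox10 UMIs lay near it. By the diet average, Sox10 was at 1.17, Nefl at -1.07 and Adrb3 at 0.27, with adjusted p of 0.298 to 0.848 (edgeR). By the temperature average they were at -0.51, -0.01 and -0.08, with adjusted p of 0.795 to 0.994. Npy, which rose with diet, stood at 118 and 377 CPM in DIO STN, 27.6 and 30.6 in DIO TN, 14.6 and 13.3 in ND STN, and 23.1 and 17.7 in ND TN.

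No nerve list other than the sympathetic one was called in any of the 7 comparisons. By diet, the medians were 0.02 for 17 Schwann cell and myelin genes (adjusted p = 0.978), -0.07 for 12 neuron and axon genes (0.851), 0.15 for 9 cholinergic and sensory neuron genes (0.755), 0.04 for 19 neurotrophic factors and receptors (0.851), 0.03 for 28 axon guidance genes (0.851) and 0.42 for 7 adrenergic receptors (0.305). By temperature they were -0.17 (0.752), -0.24 (0.683), 0.55 (0.327), 0.02 (0.747), 0.07 (0.446) and 0.39 (0.475). In spots thinned to 2000 UMIs, the share with at least 2 UMIs of Schwann cell genes was 6.08% ± 1.32 (SD, n = 4) in DIO and 6.05% ± 1.37 (n = 4) in ND, a difference of 0.0225 percentage points (exact permutation test, two-sided, p = 1). It was 6.64% ± 1.23 in STN and 5.49% ± 1.11 in TN, a difference of 1.16 points (exact permutation test, p = 0.200). Section values ran from 4.65% (95% Wilson interval 4.02 to 5.38, DIO TN 1) to 7.97% (7.09 to 8.94, ND STN 2). The smallest p that the 70 splits allow is 0.0286. Thinning left out 1199 spots in DIO STN 2, 394 in DIO STN 1 and 18 to 280 in the others; without thinning the shares were 58.8% ± 24.5 in DIO and 71.6% ± 5.30 in ND. Mbp, Cadm4 and Egr2 held 83.3% to 94.7% of these UMIs, so the share mostly followed these genes. Whether it tracks nerve in this tissue was not tested, so equal shares do not show equal innervation. Without Mbp, Cadm4 and Egr2, in a measure chosen after the data had been seen, the share of spots with at least 1 UMI was 4.44% ± 1.99 in DIO and 4.84% ± 0.302 in ND (difference -0.404, exact permutation p = 0.714), and 4.19% ± 1.17 in STN and 5.10% ± 1.49 in TN (difference -0.913, exact permutation p = 0.371). The background of the receptor genes, scaled to the 12 genes of this measure, was 1.25% in DIO STN 1, 0.299% and 0.308% in DIO TN, 0.0694% in DIO STN 2 and 0.0400% to 0.1% in ND. Moran's I, a measure of clustering in space, was -0.0115 to 0.109 over the sections, and 0.00961 to 0.147 without Mbp, Cadm4 and Egr2. With these genes in, neither the diets (0.0353 ± 0.0526 and 0.0277 ± 0.0260, exact permutation p = 0.886) nor the temperatures (0.0263 ± 0.0172 and 0.0368 ± 0.0558, exact permutation p = 0.8) differed.

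**Figure D4:**
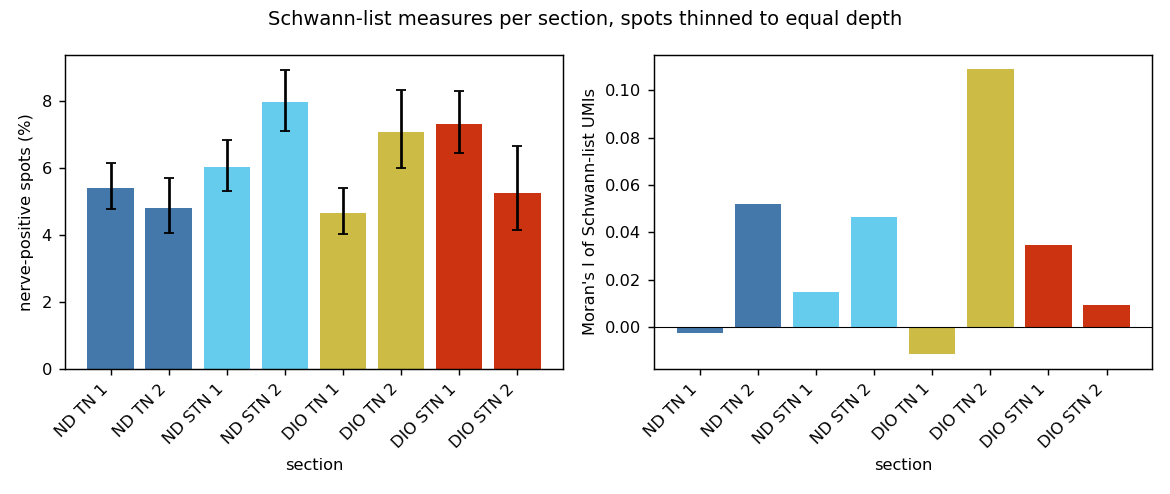
Share of spots with at least 2 UMIs of Schwann cell genes after thinning to 2000 UMIs (left, percent of spots, bars with 95% Wilson intervals) and Moran's I of these UMIs (right), for each section, coloured by group. The shares lie between 4.65% and 7.97%, and the groups overlap. Mbp, Cadm4 and Egr2 hold 83.3% to 94.7% of the Schwann cell gene UMIs before thinning.

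The other lists that no comparison called were markers of islets, fibroblasts, endothelium, and pericytes with smooth muscle, and genes of inflammatory fibroblasts, thermogenic adipocytes, fatty acid synthesis, oxidative phosphorylation and keratinisation. By diet their medians were 0.35, -0.09, -0.18, -0.22, 0.32, 0.37, -0.10, 0.00 and -0.21 in that order, with adjusted p of 0.115 to 0.884 (camera, preset correlation). The Npy UMIs of the DIO STN sections were spread over many spots: 54.5% of spots in DIO STN 1 and 40.1% in DIO STN 2 held at least 1, against 26.3% and 30.5% in DIO TN and 15.1% to 24.6% in ND, although both DIO STN sections had fewer UMIs per spot. The 10% of spots with most Npy held 53.0% of it in DIO STN 1, 81.7% in DIO STN 2, where 49.6% of spots had fewer than 2000 UMIs, and 57.3% to 76.3% in the other 6 sections.

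**Figure D5:**
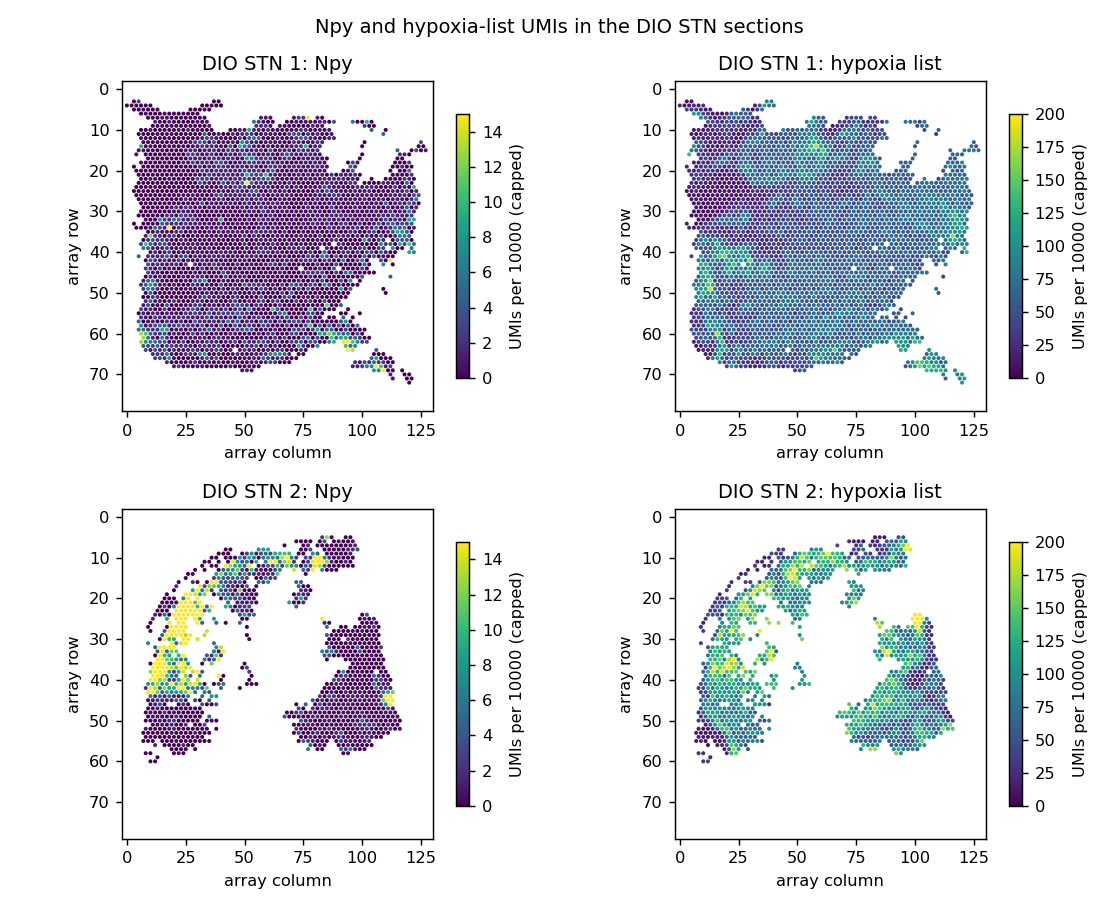
Maps of the DIO STN sections with each spot at its grid row and column, for spots of at least 2000 UMIs, coloured by Npy UMIs (left) and hypoxia list UMIs (right) as a share of its UMIs, capped at the top of each scale. The 10% of all spots with most Npy hold 53.0% of its UMIs in DIO STN 1 and 81.7% in DIO STN 2.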

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

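The tests of explanations below were chosen after the results had been seen, except those on hypoxic tissue and on lymphoid areas, whose predictions were written before their values.

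Some results stood out because the effect of diet differed between temperatures. Klf4 was the only gene past the interaction test (log2 2.79, adjusted p = 0.0233). The lists that camera called for the interaction had no member past the test over all genes and lost the call with an estimated correlation. Their medians, each followed by the adjusted p and by the adjusted p with an estimated correlation, were 1.31 for immediate early and stress genes (2.89e-13; 0.0921), 1.3 for glucocorticoid response genes (8.18e-11; 0.459) and 0.54 for unfolded protein response genes (1.36e-08; 0.0921). For hypoxia genes they were 1.24 (4.63e-07, 0.590), for erythrocyte genes 3.50 (1.16e-06, 0.463), for glycolysis genes 0.87 (1.49e-05, 0.590) and for epithelial markers 0.57 (0.000109, 0.540). For interferon response genes they were -1.28 (0.000186, 0.731), for proliferation genes -0.41 (0.00392, 0.709), for epithelial-mesenchymal transition genes 0.73 (0.00519, 0.731) and for fatty acid uptake and oxidation genes 0.52 (0.00519, 0.600). For skeletal muscle genes they were -1.59 (0.00591, 0.837), for sympathetic neurotransmitter genes 0.97 (0.0159, 0.459) and for antigen presentation genes 0.67 (0.0214, 0.845). For adipocyte markers they were 0.64 (0.0278, 0.837), for cholesterol synthesis genes 0.35 (0.0278, 0.837) and for immune checkpoint genes 0.71 (0.0278, 0.8). Adjusted over the list alone, 11 immediate early genes were higher and 1 lower; 7 unfolded protein response, 7 glucocorticoid response, 6 erythrocyte, 5 glycolysis, 4 hypoxia, 3 fatty acid, 2 epithelial, 2 transition, 2 cholesterol and 1 sympathetic gene were higher; and 3 proliferation genes were lower.

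The DIO STN sections stood apart, and 3 explanations of the 1607 genes called for diet in STN were tested. A difference between 2 sets of 4 sections run together would part ND TN, which shares library numbers with DIO STN, from ND STN. The called genes differed there by a median of 0.0660 in the called direction, against 0.907 for diet, and 1016 of 1607 had the same sign. The 0.907 is raised by the choice of the genes on that comparison. The gap still argues against such sets as the main source, unless a temperature effect in ND offset their difference. With spots matched to the lower hypoxia levels of ND sections, the median of the 1583 called genes outside the hypoxia list went from 0.898 to 0.575, and that of the hypoxia list from 1.33 to 0.397. Only 5.54% and 6.16% of the DIO STN spots remained and 0 genes were called by edgeR, so a larger share of hypoxic tissue stays open as part of the difference. With sections of a shared code summed, 0 genes were called, but this leaves 5 libraries for 4 groups, with a spread from DIO TN alone, so few calls were possible, and the median of the called genes was 0.931. A single tumour or its handling was thus not tested by this count and stays open.

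The class II genes were 3.12 lower in DIO by their median log2 fold change. That lies 2.96 below the macrophage list (a difference of -2.96), and the ratio of class II to macrophage UMIs was 0.0214 to 0.0643 in DIO sections and 0.192 to 0.429 in ND sections, which excludes an even loss of macrophages. A loss of a class II-rich subset or of dendritic cells was not tested. Without the region led by immunoglobulin genes, the difference in mean log2 class II level was -2.84, against -3.15 with it, which excludes lymphoid areas in the ND sections as the main source.

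Background probe signal set some DIO sections apart. The 1178 olfactory and vomeronasal receptor genes, which are not known to be active in pancreas, had a mean of 10.6 UMIs in DIO STN 1, 3.72 in DIO TN 1 and 2.47 in DIO TN 2, above all ND sections (0.770 to 1.98), and 0.404 in DIO STN 2. The share of these genes with a UMI was 98.9% in DIO STN 1, 90.6% and 81.2% in DIO TN, 26.1% in DIO STN 2, 44.8% and 41.5% in ND TN, and 73.6% and 22.3% in ND STN. The cause was not tested.

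Splits of the 8 sections into 4 and 4 were fitted as 2 groups. For diet, 2 of the 35 splits called at least as many genes as the diet split, itself among them, which called 1; the split by replicate number called 8, several times as many, which points to a structure of the sections that runs with the replicate number and whose source is not known. For temperature the real split called 0, so that 35 of 35 splits called as many or more by construction, which says nothing on chance; the highest was 8. By unadjusted p under 0.05, these splits had 1793, 1679 and 1098 genes for diet, replicate number and temperature (edgeR); splits that follow no label had 2063 and 1802, more than diet, and several others had more than temperature.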

How the results depend on the processing

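Alternatives were fixed beforehand unless said to be added after seeing the data, the cause of a change was not tested, and counts are in the order diet average, temperature average, diet in STN, temperature in DIO and interaction, against 201, 48, 1607, 1562 and 1 genes. Diet in TN and temperature in ND stayed at 0 by edgeR (773 and 387 genes at an unadjusted p under 0.05) in all settings but DESeq2, which called 77 and 3. With library size alone the counts were 795, 312, 3137, 2901 and 258, by DESeq2 1661, 1220, 3113, 2999 and 1280, and in the spots above each section's median of the epithelial list 1176, 572, 2885, 2752 and 387. Without the filter, temperature reached 80 (44 higher and 36 lower, against 40 and 8), and the higher and lower counts were 98 and 134 for diet (145 and 56 with it), 469 and 1171 for diet in STN (825 and 782) and 434 and 1012 for temperature in DIO (772 and 790). With the replicate number as a block the counts were 788, 163, 2870, 2622 and 330; the correlations of same-numbered deviations between groups were 0.15 to 0.5 for 5 of 6 pairs of groups and -0.04 for DIO TN with DIO STN, so the numbers were not taken to pair the sections, though a shared structure is not excluded, and list calls by block were 14, 13, 15, 12 and 18. With sections of a shared code summed, which leaves 5 libraries and a spread from DIO TN alone, the counts were 0, 2, 0, 28 and 0. A fit of 2 groups gave 1 for diet and 0 for temperature, and fits of only the 4 sections compared 0 for diet in STN and 26 for temperature in DIO. Among alternatives added after seeing the data, spots of at least 5000 UMIs gave 31 for temperature, the spots below each section's median of the hypoxia list gave 30, 5, 966, 905 and 0, and genes of mean log2 CPM of 3 or more gave 363, 105 and 147 for diet, temperature and interaction; thinning all sections to the smallest total moved no count by over 1.5 times. Leaving out each section in turn gave 0 to 152 for diet, 0 to 26 for temperature, 5 to 1131 for diet in STN, 0 to 1321 for temperature in DIO and 0 to 4 for the interaction. List calls were 15, 11, 17, 14 and 17, and 14 and 10 for diet in TN and temperature in ND. With the correlation estimated from the data they were 0 in all 7 comparisons. Leaving out sections gave 11 to 18, 13 to 16, 10 to 19, 11 to 22 and 10 to 25, and for diet in TN 9 to 21 and temperature in ND 9 to 21. Of 9461 alternative values for single genes, 7954 were the same, 344 stronger, 1163 weaker and 0 reversed, with 755 of the weaker ones from leaving out a section. Stronger and weaker mean a call gained or lost, and reversed means a changed sign of a gene called in the main fit. A changed sign of a gene not called there was not counted as reversed. No alternative of the nerve, acinar or clustering measures changed a call.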

Other observations

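The tests of Npy below were chosen after its level had been seen, and the regions were described without a test between groups.

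The sections differed in tissue make-up in ways that no comparison covers. Region 6, led by the immunoglobulin genes Igkc, Ighm and Igha, held 29.1% of the clustered spots of ND TN 2 and 38.9% of those of ND STN 2, and at most 0.192% in any other section. Region 1, led by the gastric genes Tff2, Dmbt1 and Gkn3, held 46.5% of ND TN 1 and 28.7% of ND STN 1. Region 4, led by Lypd2, Mmp7 and Ltf, held 28.9% of DIO TN 1 and 33.6% of ND STN 1, and region 5, led by the chloride channel gene Cftr and by Bpifb1, held 35.1% of ND TN 2 and 23.9% of ND STN 2. Region 10, led by Bpifb1, F5 and Thbs4, held 51.7% of DIO TN 2. Skeletal muscle, region 11 with Acta1, Atp2a1 and Ckm, held 14.8% of DIO TN 2 and 0.0993% to 8.20% elsewhere.

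T cell transcripts were rare in DIO tumours. The CD8 chain gene Cd8b1 had 3 and 1 UMIs in the DIO STN sections, 3 and 0 in the DIO TN sections and 22 to 148 in the ND sections. The T and NK cell list held 9.58 to 14.6 CPM in DIO and 22.5 to 79.6 CPM in ND. Its highest ND totals were 79.6 CPM in ND TN 2 and 44.2 CPM in ND STN 2. In these sections the region led by immunoglobulin genes held 29.1% and 38.9% of clustered spots. ND TN 1 and ND STN 1, where it held at most 0.192%, had 25.2 and 22.5 CPM, still above all DIO sections. The list was not tested without that region. How far that region adds to the list medians of -2.23 by diet and -2.70 for diet in TN is thus open.

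For the higher Npy of DIO STN, Th and Dbh, the enzymes of noradrenaline synthesis, had 13 UMIs together against 13072 of Npy in these sections, or 0.0994%, and the neuron and axon list had a median of -0.35 for diet in STN, which excludes transcripts of sympathetic cell bodies as the main source. Axons carry little RNA, so nerve fibres could be missed by this 0.0994%. Across thinned spots Npy went with the hypoxia list, at Spearman coefficients of 0.121 in DIO STN 1 and 0.322 in DIO STN 2, against -0.0642 and -0.0237 for the Schwann cell list and -0.0154 and -0.123 for the neuron list. It also went with the glucocorticoid list (0.107 and 0.277), the immediate early list (0.0869 and 0.115) and, in DIO STN 2, the epithelial list (0.223); the adipocyte coefficient there was 0.186, although spots with Npy held fewer adipocyte UMIs on average (5.45 against 6.53), while in other sections the hypoxia coefficient was -0.0228 to 0.117. In DIO STN 2 it ran against fibroblast (-0.149), macrophage (-0.136) and neutrophil markers (-0.129).

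A hypothesis that may account for these values is that cells of hypoxic tissue, of a type not settled here, make Npy in obese, cold-housed mice, given the coefficient of 0.121 or more with hypoxia genes. The glucocorticoid coefficients (0.107 and 0.277) were close to these, so the values do not single out hypoxia. Across sections, DIO STN was highest in both Npy and the hypoxia list. Yet ND STN 1, with 3242 CPM of the hypoxia list, held 14.6 CPM of Npy. That was below DIO TN, with 27.6 and 30.6 CPM of Npy and 2059 and 1850 CPM of the hypoxia list. Staining for NPY, tyrosine hydroxylase and a hypoxia marker on sections of new animals would test the hypothesis. More animals per group, with groups spread over slides, would part slide, animal and group.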
